A study of Mus musculus with 32 samples.

How the data were processed

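Total RNA from mouse macrophages, grown from bone marrow in M-CSF, was measured on 1-colour Agilent arrays labelled with Cy3, per the labels' protocols. The 32 arrays form 16 groups of 2, made of 8 genotypes that were each left unstimulated or treated for 12 h with 300 ng/mL Pam3CSK4. The unstimulated arrays are labelled 0 min, so there is no untreated array at 12 h. Each bioreplicate gave 1 unstimulated and 1 stimulated array, and the labels assign every mutant bioreplicate to a numbered comparison group with a wild-type bioreplicate. The Affymetrix arrays that the series description mentions are not analysed here.

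The deposited values, 1 table with 35532 rows and 32 columns, are on a log2 scale, as judged from their range. Array medians lay between 6.4 and 6.48 and lower quartiles between 5.39 and 5.41. How the authors extracted features, corrected background, normalized arrays and merged probes into 1 row per name is not given in the sources used here. Between 15.8% and 16.7% of the values of an array recurred exactly in the first array. The table holds no detection calls, so a signal near the lower quartile was treated as close to background. Of the row names, 20146 equal a current gene symbol in the RefSeq annotation of assembly GRCm38.p6, 2693 are a unique older symbol and 12693 match neither. Symbols are printed as in the table, with the current one where it differs.

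Values were used as deposited. Rows with at least 2 arrays above the array's median were tested, which left 20753. A mean for each of the 16 groups was fitted with limma 3.58.1 in R 4.3.3, with 16 residual degrees of freedom and 3.32 prior degrees of freedom from eBayes, and the tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The comparisons were the mean response of the 3 wild-type groups, each mutant against its own wild type in each condition, and each mutant's response minus that of its wild type, termed the response difference. Changes are log2 differences with the standard error of the limma fit.

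A total of 23 pathway lists and 13 lists of cell-type or sex-linked transcripts were tested with limma's camera, adjusted over the lists within a comparison. The preset correlation between genes was 0.01, and each test was repeated with an estimated correlation. The B cell and mast cell lists had 2 tested members each and were not tested. The induced-gene shift is the median response difference over genes that rose at least 4-fold in the mean of the wild-type groups not serving as that mutant's control, tested with camera. Correlations of response differences are across genes, which are not independent replicates, and carry no p-value.

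The comparisons, lists and alternatives were fixed before the data were examined, as was the rule for the genes named. The rule takes the mutated genes and, for the wild-type response and each stimulated comparison, the 10 largest rises and 10 largest falls among called, named genes whose arrays did not overlap between groups. Response differences and unstimulated comparisons give 5 each way, the former without the condition on overlap. For lists, up to 4 members with the largest change were eligible, and Il12b, Il6, Tnf, Il1b, Nos2, Ptgs2 and Il10 were given for each mutant after stimulation.

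The alternatives were other filters, quantile normalization, centring on the 75th percentile, eBayes with trend and robust options, fits limited to the groups compared, and a fixed or random block. Across genes, deviations from the group means correlated at r = 0.305 to 0.767 between the arrays of a bioreplicate, which the labels pair, and at 0.343 to 0.752 between the arrays of a comparison group. The fixed block was the comparison group for mutant against wild type and the bioreplicate for responses, and its values are called blocked. Each array of the groups compared was also left out in turn, where the array left alone in its group is assumed to vary like the other groups. The level of stromal fibroblast markers was added as a covariate after seeing the data. Counts of calls with it use 1 slope for both conditions. It differs between mutant and wild type, so calls can be lost to larger standard errors without a smaller difference. Averaging the probes of a gene was planned but could not be run on 1 row per name.

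The scripts' tests were checked on simulated data with the real spread over 20753 genes, with 100 genes changed 2-fold and 100 changed 4-fold. Without a block, 84% and 97% of these were recovered for the wild-type response. For Sharpin cpdm against Sharpin WT they were 46% and 87% after Pam3CSK4, 42% and 83% unstimulated, and 6% and 73% for the response difference. Of the unchanged genes 0, 9, 9 and 0 were called in these 4 comparisons, and 9, 18, 10 and 4 with the replicate block. For stimulated Sharpin cpdm that was 18 of 159 calls with the block and 9 of 142 without it. Unstimulated it was 10 of 138 and 9 of 134. Calls in these comparisons can thus exceed the nominal share of false ones, most clearly in the blocked fit after Pam3CSK4. For the closing tests a curve was removed from each array by limma's fast cyclic loess over all 35532 rows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.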

Results

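Expression was measured in macrophages from 8 mouse genotypes, unstimulated and after 12 h with Pam3CSK4, a synthetic lipopeptide that activates TLR2. The unstimulated arrays are labelled 0 min. In a response, the effects of Pam3CSK4 and of 12 h in culture therefore cannot be told apart. Each of the 16 groups had 2 bioreplicates. Sharpin cpdm was compared with Sharpin WT, Ikbkg panr2 with Ikbkg WT, and the 3 knockouts, Nfkb1 KO, Il10 KO and Atf3 KO, with the same Bl6 WT arrays. Per the series description, the comparisons address how each mutation alters the macrophage response to a TLR2 ligand. Precision is limited by the 2 arrays per group: the median standard error was 0.27 for a mutant against its wild type and 0.381 for a response difference. The p-values of the main fit measure the spread between the arrays of a group, and leave the pairing by bioreplicate and comparison group aside. The arrays of a bioreplicate correlated (consensus correlation 0.587), so the error of a response difference also reflects the ignored pairing. In simulated data with such pairing, 6% of 2-fold response differences were recovered without a block and 19% with it. Unchanged genes called were 0 and 4. The labels do not say that the bioreplicates came from separate animals. Genes ranked by size of change had both mutant arrays outside both wild-type arrays, except for response differences.

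The transcript of the mutated gene differed in some mutants. Sharpin, a subunit of the linear ubiquitin chain assembly complex, was lower in Sharpin cpdm than in Sharpin WT by -1.46 ± 0.29 after Pam3CSK4 (adjusted p = 0.00482) and by -1.32 ± 0.29 unstimulated (0.0414). The first call was lost without Sharpin WT stimulated replicate II, and the second held only without Sharpin WT unstimulated replicate I. In groups other than Sharpin cpdm the mean Sharpin signal was 13.75 to 14.72. Ikbkg, which encodes NEMO, the regulatory subunit of the IKK complex, differed in Ikbkg panr2 by -0.15 ± 0.22 unstimulated and -0.47 ± 0.22 stimulated (adjusted p = 1 and 0.46). Nfkb1, which encodes p105 and p50, differed in Nfkb1 KO by -0.74 ± 0.24 and -0.39 ± 0.24 (adjusted p = 0.558 and 0.587). In arrays labelled Atf3 KO the signal named Atf3, a transcription factor of the ATF family, was 1.98 ± 0.48 above Bl6 WT unstimulated (adjusted p = 0.337, blocked 0.0431) and 1.64 ± 0.48 above it stimulated (0.545, blocked 0.0777). In Il10 KO the Il10 signal was 2.35 ± 0.52 above Bl6 WT unstimulated (adjusted p = 0.056, blocked 0.00952) and differed by -2.46 ± 0.52 after Pam3CSK4 (0.0159), a call lost without any 1 of the 4 arrays. Where these probes lie relative to the targeted exons is not given in the sources used here.

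In wild-type macrophages the antimicrobial and inflammatory effector list was higher after Pam3CSK4, and 18 of its 20 tested members rose. They included Saa3, an acute-phase protein (+10.30 ± 0.49), the scavenger receptor Marco (+8.42 ± 0.43), the itaconate-producing enzyme Irg1, now Acod1 (+8.31 ± 0.47), and the iron-sequestering Lcn2 (+7.92 ± 0.32). Among 15 inflammatory cytokines 13 rose, with Il1b at +9.95 ± 0.49, Il6 at +9.07 ± 0.40, Il1a at +7.39 ± 0.38 and the granulocyte growth factor Csf3 at +6.54 ± 0.45. Of 19 chemokines 16 rose, among them the neutrophil attractants Cxcl3 (+7.95 ± 0.45) and Cxcl1 (+5.58 ± 0.41) and the T cell attractant Ccl5 (+6.56 ± 0.39). NF-kB subunits and feedback regulators rose in 16 of 19 cases, including Zc3h12a, an RNase that degrades cytokine mRNA (+3.97 ± 0.29), and Tnfaip3, the ubiquitin-editing protein A20 (+2.91 ± 0.22). The camera adjusted p was 1.3e-20, 1.96e-10, 2.16e-09 and 3.02e-11 for these lists in turn. With an estimated correlation the adjusted p was 0.00352, 0.0139, 0.0139 and 0.0383. Adjusted over the list alone, 18, 13, 16 and 16 members rose and 1 NF-kB member fell.

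Interferon-stimulated genes rose in 27 of 30 cases (28 adjusted over the list alone), with the GTPase Gbp2 at +3.58 ± 0.41 and the ubiquitin-like Isg15 at +2.99 ± 0.27 (adjusted p = 5.52e-13; adjusted p = 0.299 with an estimated correlation). Glycolysis and hypoxia genes rose in 16 of 19 cases (17 adjusted over the list alone), led by Pfkfb3, which makes an activator of glycolysis (+3.58 ± 0.15; adjusted p = 1.23e-10, and adjusted p = 0.0804 with an estimated correlation). Of the IL-10 and STAT3 response genes 9 of 11 rose and 2 fell, both over all genes and adjusted over the list alone, with the signalling inhibitor Socs3 at +7.05 ± 0.30 (adjusted p = 1.07e-05; adjusted p = 0.0564 with an estimated correlation). Cell cycle genes fell in 25 of 27 cases, also adjusted over the list alone, including cyclin A2, Ccna2 (-4.10 ± 0.34), and the mitotic kinase Plk1 (-3.70 ± 0.30; adjusted p = 2.48e-14, and adjusted p = 0.259 with an estimated correlation). Among 16 lysosome genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), with the glycoprotein Gpnmb at -1.80 ± 0.28 (adjusted p = 0.00479; adjusted p = 0.436 with an estimated correlation). TLR receptors and adaptors, the integrated stress response, AP-1 and immediate early genes, MHC class I presentation, NRF2 and oxidative stress, and heat shock and chaperones also rose as lists. Their adjusted p was 0.00656 to 0.0202, and their adjusted p was 0.299 to 0.481 with an estimated correlation.

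Other large rises were those of the acute-phase proteins Saa1 (+8.20 ± 0.38) and Hp (+8.15 ± 0.46) and complement factor B, Cfb (+7.76 ± 0.32). The largest falls were those of the organic anion transporter Slco2b1 (-5.96 ± 0.29), the Ras activator Rasgrp3 (-5.53 ± 0.19), Cd28, known as a T cell costimulatory receptor (-5.44 ± 0.37), and Pcp4l1 (-5.02 ± 0.23). The iron exporter Slc40a1 (-4.74 ± 0.47), the spindle protein Aspm (-4.62 ± 0.27) and the linker histone Hist1h1b, now H1f5 (-4.61 ± 0.59), fell too. Gas6, a ligand of TAM receptors (-4.48 ± 0.14), the mannose receptor Mrc1 (-4.25 ± 0.26) and Tmem132a (-4.12 ± 0.23) completed the 10. Il12b, a subunit of IL-12 and IL-23, rose by at least 4.63 ± 0.32, the inducible nitric oxide synthase Nos2 by 4.06 ± 0.28, the prostaglandin synthase Ptgs2 by 6.74 ± 0.30, Tnf by 3.14 ± 0.39 and the anti-inflammatory Il10 by 1.98 ± 0.30. Unstimulated Il6 lay at 5.03 to 5.30 in the wild-type groups, under the lower quartile of the arrays, as did unstimulated Il1a and Il12b and stimulated Slco2b1 in each wild-type group and unstimulated Csf3 and Cxcl3 in Bl6 WT. Their fold changes are therefore lower bounds. In all, limma called 8489 of 20753 genes, 4015 higher and 4474 lower, and 1204 rose and 1635 fell at least 2-fold. Of the 28 genes past the threshold that were ranked by size or fixed in advance, 27 passed whichever of the 12 arrays was left out, as did the other list members named.

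After Pam3CSK4, Sharpin cpdm macrophages had lower levels of several inflammatory cytokines than Sharpin WT. Of 15 cytokines 6 were lower and none higher (8 adjusted over the list alone), among them Il1a (-5.84 ± 0.67), Csf3 (-3.48 ± 0.77), Il6 (-3.39 ± 0.70) and Il12b (-2.99 ± 0.55). Antimicrobial and inflammatory effectors were lower in 6 of 20 cases (8 adjusted over the list alone), with Nos2 at -3.0 ± 0.48, the collagenase Mmp13 at -3.25 ± 0.55, Lcn2 at -2.73 ± 0.56 and the prostaglandin E synthase Ptges at -2.55 ± 0.18. Stimulated Nos2 averaged 13.6 in Sharpin WT and 10.6 in Sharpin cpdm, against 9.6 in Bl6 WT and 10.8 in Ikbkg WT. Sharpin cpdm thus lay between the other wild types, and the difference in Nos2 rests on a high Sharpin WT level. Ptgs2 was lower by -1.93 ± 0.52 (adjusted p = 0.0372), a call lost without any 1 of the 4 arrays, whereas Tnf differed by -0.10 ± 0.67 (adjusted p = 0.982) and Il1b by -2.37 ± 0.85 (0.144). Chemokines were lower in 4 of 19 cases (7 adjusted over the list alone), including Cxcl3 (-5.23 ± 0.79), the dendritic-cell-derived attractant Ccl17 (-4.08 ± 0.48) and Ccl5 (-2.76 ± 0.67). The adjusted p of these lists was 3.68e-08, 9.64e-09 and 0.000981. With an estimated correlation the adjusted p was 0.0869, 0.0869 and 0.225.

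Il10 was higher in stimulated Sharpin cpdm than Sharpin WT, by 3.41 ± 0.52 (adjusted p = 0.000614), and so were the lipid-sensing nuclear receptor Pparg (+3.37 ± 0.41), the sphingomyelinase Smpd3 (+3.21 ± 0.45) and the protocadherin Pcdh19 (+3.13 ± 0.43). Stimulated Il10 stood at 9.57 and 7.80 in the Sharpin WT arrays and averaged 12.10 in Sharpin cpdm. It averaged 10.57 in Bl6 WT and 9.97 in Ikbkg WT, so the size of the difference rests in part on a low Sharpin WT level. Further genes with higher signal were Fgl2 (+3.67 ± 0.83), the growth factor Pdgfc (+3.37 ± 0.76), the secreted macrophage protein Cd5l (+3.32 ± 0.88), the complement inhibitor Cd55 (+3.12 ± 0.57), Ndrg1 (+2.97 ± 0.50) and Dennd2a (+2.95 ± 0.54). The lowest signals relative to wild type, besides Il1a and Cxcl3, were the activin subunit Inhba (-5.78 ± 0.66), the arginine transporter Slc7a2 (-5.71 ± 0.26), arginase, Arg1 (-5.24 ± 0.88), and the protease inhibitor Timp1 (-4.37 ± 0.53). Transcripts typical of matrix-producing cells also belonged to the 10 lowest: the collagens Col1a1 (-5.08 ± 1.20) and Col1a2 (-4.63 ± 1.08), fibronectin, Fn1 (-4.83 ± 0.98), and Ctgf, now Ccn2 (-4.41 ± 0.89). Cell cycle genes were higher in 8 of 27 cases (11 adjusted over the list alone), with Plk1 at +2.73 ± 0.53 (adjusted p = 4.38e-09; adjusted p = 0.365 with an estimated correlation), but with the stromal marker level as a covariate, an alternative chosen after seeing the data, the list's median went from 1.30 to -0.003. MHC class II genes were lower in 4 of 8 cases, also adjusted over the list alone, with H2-Ab1 at -3.58 ± 0.72 (adjusted p = 8.18e-06; adjusted p = 0.225 with an estimated correlation), and with that covariate its median was -0.24 (adjusted p = 0.695). Glycolysis and hypoxia genes were lower in 2 of 19 cases (9 adjusted over the list alone), including the oxygen sensor Egln3 (-2.36 ± 0.46), and NRF2 genes in 2 of 13 (2 adjusted over the list alone), including the cystine transporter Slc7a11 (-3.50 ± 0.48). The adjusted p of the last lists was 2.4e-06 and 0.000538, and the adjusted p was 0.225 for both with an estimated correlation.

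These gene groups moved with the stromal fibroblast markers, of which 7 of 10 were lower in stimulated Sharpin cpdm (10 adjusted over the list alone; median -2.29, adjusted p = 1.11e-09, and adjusted p = 0.169 with an estimated correlation). In total 998 genes differed, 423 higher and 575 lower, and 2342 in the blocked fit. The count was 211 without Sharpin cpdm replicate II, 218 without Sharpin WT replicate II, 526 without Sharpin cpdm replicate I and 644 without Sharpin WT replicate I, all stimulated. With the stromal marker level as a covariate 143 genes passed. Of the 25 genes past the threshold that were ranked by size or fixed in advance, 10 passed whichever array was left out, and 13 passed without Sharpin cpdm stimulated replicate II. Of the other list members named, Ccl17, Mmp13, Ptges and Slc7a11 passed each time, and Ccl5 was lost without any 1 of the 4 arrays. Lcn2, H2-Ab1 and Egln3 were lost without replicate II of either genotype, Csf3 without Sharpin WT replicate I or Sharpin cpdm replicate II, and Plk1 without Sharpin WT replicate II or Sharpin cpdm replicate I.

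**Figure D1:**
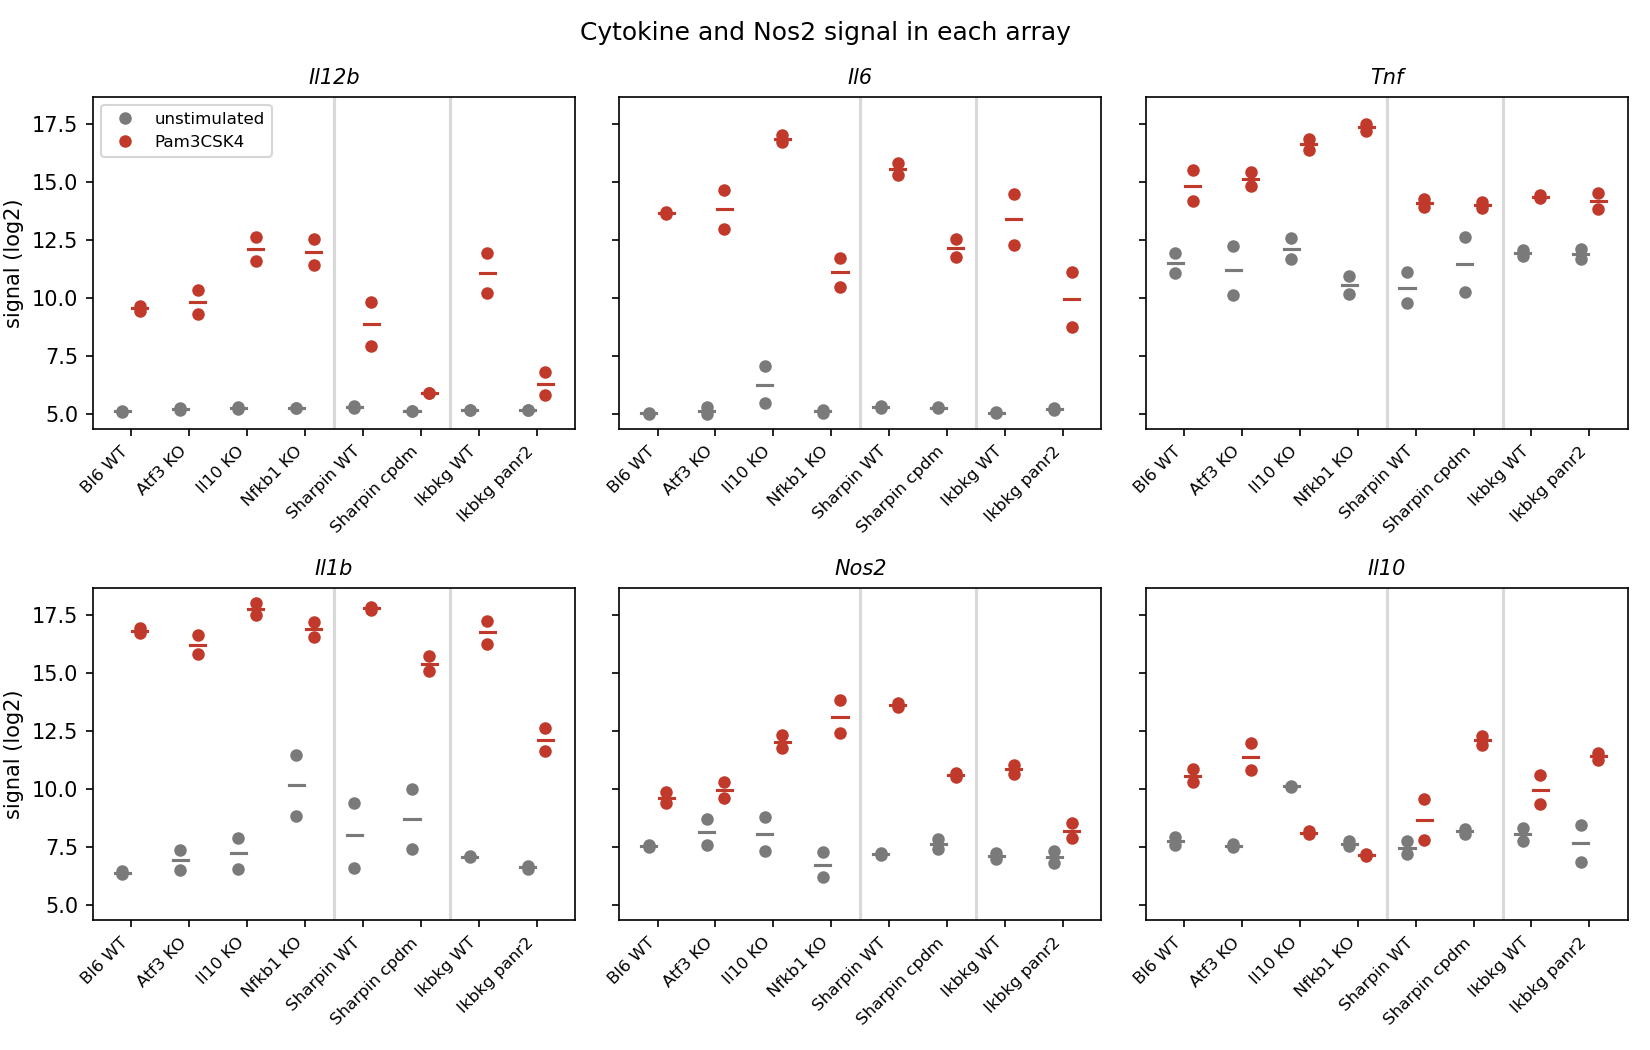
Signal (log2, vertical axis) of 5 cytokine genes and Nos2 in each array by genotype; points are single arrays, bars the means of 2, grey unstimulated and red after Pam3CSK4. Stimulated Il12b averaged 5.88 in Sharpin cpdm and 6.30 in Ikbkg panr2, against 8.87 and 11.07 in their wild types.

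Unstimulated Sharpin cpdm macrophages already differed from Sharpin WT. Of 19 NF-kB subunits and feedback regulators 4 were higher (13 adjusted over the list alone): the adaptor Traf1 (+2.85 ± 0.54), the NF-kB inhibitor Nfkbie (+1.66 ± 0.35), the ubiquitin ligase Birc3 (+1.47 ± 0.32) and Nfkb2 (+1.31 ± 0.27). That list passed with an adjusted p of 8.36e-26, and with an adjusted p of 0.00353 with an estimated correlation. Antimicrobial and inflammatory effectors were higher too (adjusted p = 4.87e-13; adjusted p = 0.0119 with an estimated correlation), with 1 of 20 called, the formyl peptide receptor Fpr2 (+1.78 ± 0.33), and 10 adjusted over the list alone. The AP-1 subunit Junb was higher by 2.12 ± 0.22 (adjusted p = 7.8e-05), Cd55 by 2.72 ± 0.57, the MHC class I gene H2-Q8 by 2.52 ± 0.44 and Mefv, which encodes pyrin, by 2.46 ± 0.40. The largest falls relative to wild type were those of Col1a1 (-5.66 ± 1.20), Col1a2 (-5.36 ± 1.08), Ctgf (-5.36 ± 0.89), Fn1 (-5.36 ± 0.98) and the smooth muscle myosin light chain Myl9 (-5.04 ± 0.82).

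The stromal fibroblast list was lower in the same unstimulated arrays, with 6 of 10 members called (8 adjusted over the list alone), a median of -2.78 and an adjusted p of 3.44e-26 (adjusted p = 0.00632 with an estimated correlation). The 10 other lists past the threshold with the preset correlation were all higher, with adjusted p from 1.97e-10 to 0.0342, and an adjusted p of 0.145 to 0.418 with an estimated correlation. With the stromal marker level as a covariate the glycolysis and NRF2 lists among them turned to -0.29 and -0.09. In all, 97 genes differed between unstimulated Sharpin cpdm and Sharpin WT, 30 higher and 67 lower, and 202 in the blocked fit. Leaving out Sharpin cpdm replicate I gave 20, Sharpin WT replicate II 53 and Sharpin WT replicate I 305. With the stromal marker level as a covariate 1 gene passed. Of the 11 genes past the threshold that were ranked by size or fixed in advance, only Junb passed whichever array was left out, and 2 passed without Sharpin cpdm replicate I. Of the other list members named, Nfkb2 was lost without any 1 of the 4 arrays, while Nfkbie held only without Sharpin cpdm replicate II, Birc3 only without Sharpin WT replicate II and Fpr2 only without Sharpin WT replicate I.

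**Figure D2:**
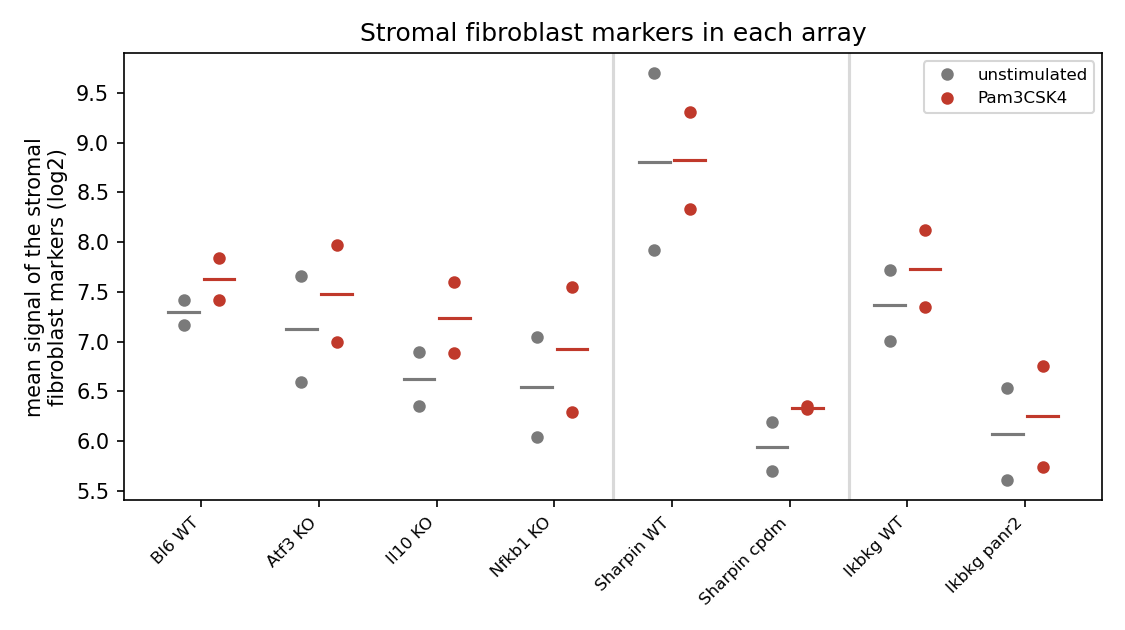
Mean signal (log2, vertical axis) of the tested stromal fibroblast markers in each array by genotype; points are single arrays and bars the means of 2, grey unstimulated and red after Pam3CSK4. Unstimulated Sharpin WT arrays stood at 7.92 and 9.70 and unstimulated Sharpin cpdm arrays at 5.70 and 6.19.

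The response itself was smaller in Sharpin cpdm for many induced genes. Over the 364 genes induced at least 4-fold in the other wild-type groups, the median response was 2.83 in Sharpin WT and 1.79 in Sharpin cpdm, and the median response difference was -1.26, with 79.9% of genes lower. It was -1.47 in comparison group I and -0.94 in group II (camera p = 1.58e-45; p = 8.89e-06 with an estimated correlation). The response difference of Cxcl3 was -7.30 ± 1.11, of Slc7a2 -6.00 ± 0.37, of Il1a -5.87 ± 0.94, of Arg1 -5.47 ± 1.25 and of H2-Ab1 -4.92 ± 1.02. It was positive for Pcdh19 (+4.53 ± 0.61), Ndrg1 (+3.36 ± 0.71), Pparg (+3.33 ± 0.59), Smpd3 (+3.26 ± 0.64) and the transcriptional coactivator Cited1 (+2.85 ± 0.43). Effector genes responded less in 6 of 20 cases (14 adjusted over the list alone), chemokines in 5 of 19 (6) and cytokines in 1 of 15 (9); the adjusted p was 8.35e-23, 9.08e-08 and 5.69e-10. With an estimated correlation the adjusted p was 0.00207, 0.0309 and 0.0219. Alternative activation genes responded less in 2 of 9 cases, also adjusted over the list alone: Arg1 and the transglutaminase Tgm2 (-2.29 ± 0.53; adjusted p = 0.000659, and adjusted p = 0.0344 with an estimated correlation). A further 6 lists had adjusted p from 5.47e-10 to 0.0151, and an adjusted p of 0.0577 to 0.686 with an estimated correlation. The response difference was called for 166 genes, 44 positive and 122 negative, for 799 in the blocked fit and for 211 with the stromal marker level as a covariate. It was called for 54 without Sharpin cpdm stimulated replicate II, 62 without Sharpin WT stimulated replicate II and 83 without Sharpin cpdm unstimulated replicate I. Of the 11 genes past the threshold that were ranked by size or fixed in advance, 5 passed whichever array was left out, and Tgm2 was lost without any 1 of the 8.

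In Ikbkg panr2 macrophages after Pam3CSK4, inflammatory cytokines were lower than in Ikbkg WT in 6 of 15 cases (8 adjusted over the list alone). The largest differences were those of Il1a (-5.91 ± 0.67), Il12b (-4.77 ± 0.55), Il1b (-4.61 ± 0.85) and Csf3 (-3.65 ± 0.77), with Il6 at -3.45 ± 0.70. Effectors were lower in 5 of 20 cases (12 adjusted over the list alone), among them Ptges (-3.05 ± 0.18) and the membrane metalloproteinase Mmp14 (-2.81 ± 0.40), and Nos2 differed by -2.63 ± 0.48 (adjusted p = 0.00522). The adjusted p was 1.2e-14 for cytokines and 1.3e-18 for effectors, and the adjusted p was 0.00365 for each with an estimated correlation. Tnf differed by -0.19 ± 0.67 (adjusted p = 1), Ptgs2 by -2.04 ± 0.52 (0.0519, blocked 0.0303) and Il10 by 1.44 ± 0.52 (0.231). Chemokines were lower in 3 of 19 cases (6 adjusted over the list alone), including Cxcl3 (-4.95 ± 0.79) and Ccl5 (-3.39 ± 0.67; adjusted p = 0.000107, and adjusted p = 0.184 with an estimated correlation). Cell cycle genes were higher in 3 of 27 cases (20 adjusted over the list alone), with cyclin B2, Ccnb2, at +2.09 ± 0.47 (adjusted p = 5.4e-18; adjusted p = 0.22 with an estimated correlation). Glycolysis and hypoxia genes were lower in 3 of 19 cases (5 adjusted over the list alone), with Pfkfb3 at -1.86 ± 0.27 (adjusted p = 1.14e-08; adjusted p = 0.209 with an estimated correlation).

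The other large falls relative to Ikbkg WT were those of Arg1 (-4.94 ± 0.88), Slc7a2 (-4.89 ± 0.26), the plasminogen activator inhibitor Serpinb2 (-4.89 ± 0.83), the amino acid oxidase Il4i1 (-4.38 ± 0.55), Cfb (-4.26 ± 0.56) and H2-Ab1 (-4.24 ± 0.72). The largest rises were those of Pparg (+2.80 ± 0.41), Smpd3 (+2.72 ± 0.45), Pcdh19 (+2.62 ± 0.43), the ribonuclease Rnase6 (+2.53 ± 0.30), the intermediate filament Nes (+2.50 ± 0.56) and the sialyltransferase St3gal6 (+2.46 ± 0.60). The transcription factor Batf3 (+2.40 ± 0.39), the adhesion molecule Nrcam (+2.35 ± 0.34), Aspm (+2.30 ± 0.47) and the kinase Stk39 (+2.25 ± 0.51) were next. The stromal fibroblast list moved with these groups, with a median of -1.28, no member called and 1 adjusted over the list alone (adjusted p = 2.22e-06; adjusted p = 0.257 with an estimated correlation). A further 9 lists had adjusted p from 0.000204 to 0.0215, and an adjusted p of 0.257 to 0.57 with an estimated correlation. In all, 369 genes differed, 120 higher and 249 lower, and 1065 in the blocked fit. The count was 63 without Ikbkg WT replicate V, 146 without Ikbkg panr2 replicate VI, 152 without Ikbkg panr2 replicate V and 230 without Ikbkg WT replicate VI, all stimulated. With the stromal marker level as a covariate 164 genes passed. Of the 22 genes past the threshold that were ranked by size or fixed in advance, 8 passed whichever array was left out. Of the other list members named, Ptges, Mmp14 and Pfkfb3 passed each time, Csf3 was lost without Ikbkg WT replicate V or Ikbkg panr2 replicate VI, and Ccl5 held only without Ikbkg WT replicate VI and Ccnb2 only without Ikbkg panr2 replicate VI.

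Unstimulated, limma called 0 genes between Ikbkg panr2 and Ikbkg WT, with 190 at an unadjusted p below 0.05 and 2 in the blocked fit. Since 190 is fewer than a share of 0.05 of the 20753 tested, the 0 calls do not show that the groups are alike. Leaving out 1 array gave 1 call without Ikbkg panr2 replicate V, 2 without Ikbkg WT replicate VI, 9 without Ikbkg panr2 replicate VI and 12 without Ikbkg WT replicate V. The stromal fibroblast list was lower there, with a median of -0.98 and no member called, also adjusted over the list alone (adjusted p = 5.35e-12; adjusted p = 0.269 with an estimated correlation), and so was the neutrophil list, with none called either way (0.019; adjusted p = 0.797 with an estimated correlation).

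Over 394 genes induced in the other wild-type groups, the median response difference of Ikbkg panr2 was -1.33, with 89.6% of genes lower, -1.42 in comparison group V and -1.23 in group VI (camera p = 1.87e-91; p = 1.63e-08 with an estimated correlation). The response difference was most negative for Ccl5 (-5.79 ± 0.95), Il1a (-5.75 ± 0.94), Cxcl3 (-5.51 ± 1.11), Cfb (-5.45 ± 0.79) and Il4i1 (-4.81 ± 0.78), and was -4.78 ± 0.78 for Il12b. It was most positive for Smpd3 (+3.21 ± 0.64), Pparg (+3.09 ± 0.59), Pcdh19 (+3.0 ± 0.61), the creatine kinase Ckb (+2.20 ± 0.41) and Cdc42ep3 (+1.46 ± 0.29). Effectors responded less in 1 of 20 cases, Ptges (-3.22 ± 0.26), with 12 adjusted over the list alone, and cytokines in 2 of 15 (7); the adjusted p was 2.24e-24 and 1.61e-16, and the adjusted p was 0.00145 and 0.00197 with an estimated correlation. A further 10 lists had adjusted p from 4.33e-17 to 0.0436, and an adjusted p of 0.0523 to 0.715 with an estimated correlation. It was called for 50 genes, 8 positive and 42 negative, for 225 in the blocked fit and for 55 with the stromal marker level as a covariate. The count was 12 without Ikbkg WT stimulated replicate V, 24 without Ikbkg panr2 stimulated replicate VI or unstimulated replicate V, and 25 without Ikbkg WT unstimulated replicate VI. Of the 11 genes past the threshold that were ranked by size or fixed in advance, 1, Cfb, passed whichever array was left out, and so did Ptges.

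**Figure D3:**
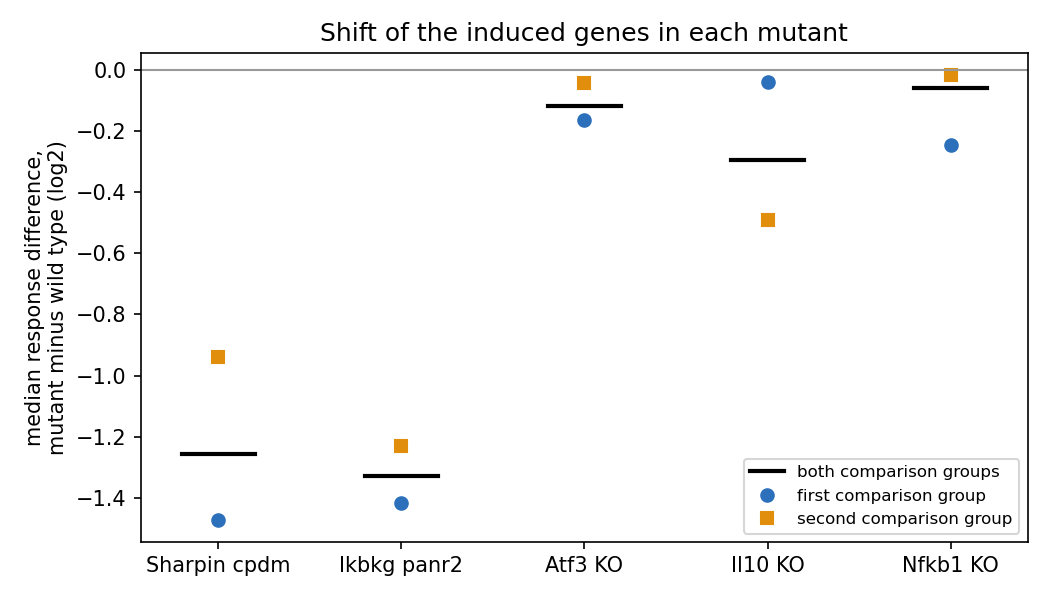
Median response difference (log2, vertical axis) of genes induced at least 4-fold in wild-type groups other than the mutant's own control; bars use both comparison groups and points a single one. Sharpin cpdm stood at -1.26 and Ikbkg panr2 at -1.33, and the 3 knockouts between -0.29 and -0.06.

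Sharpin cpdm and Ikbkg panr2, which share no array, had many called genes in common. Both had lower Il1a, Slc7a2, Cxcl3, Arg1 and Il12b and higher Pparg, Smpd3 and Pcdh19 after Pam3CSK4 than their wild types. In total 166 genes were lower in both, where 6.9 would overlap by chance, and 63 were higher in both, where 2.45 would. None was called in opposite directions. These chance values treat all tested genes as equally likely to be called. Ikbkg panr2 and Nfkb1 KO also had 37 genes lower in both (2.32 by chance), among them Arg1 and Slc7a2, and 34 called in opposite directions (6.38). Over the 8489 genes of the wild-type response, the response differences of Sharpin cpdm and Ikbkg panr2 correlated across genes with a Pearson r of 0.792 and a Spearman rho of 0.698. Those genes were chosen in part with the Sharpin WT and Ikbkg WT arrays, the controls of these mutants, which can raise r. Over all 20753 genes tested r was 0.672. Over the genes of the wild-type response it was 0.577 without Sharpin WT unstimulated replicate I. The stromal fibroblast list was lower in both after Pam3CSK4, with medians of -2.29 and -1.28, and with the marker level as a covariate the calls fell from 998 to 143 in Sharpin cpdm and from 369 to 164 in Ikbkg panr2. The overlap was not counted with that covariate. The lost calls need not mean smaller differences. With 1 slope per condition, the induced-gene shift of Sharpin cpdm was -1.299, against -1.256 without the covariate. Of the induced genes, 1 instead of 56 was then called lower for the response difference. Stimulated effects were tested against each other directly, and limma called 7 genes. Those named here were chosen after their values were seen: Enpp2, which makes lysophosphatidic acid (Sharpin cpdm minus Ikbkg panr2, +2.40 ± 0.32, adjusted p = 0.00583), and Tbc1d2 (-2.45 ± 0.34, 0.00583). Unstimulated effects differed for Junb (+2.15 ± 0.31, adjusted p = 0.0233) and Lce1i (-1.61 ± 0.24, 0.0247). For the response difference limma called 0 genes, with 146 at an unadjusted p below 0.05. That is fewer than a share of 0.05 of the 20753 tested, so the 0 calls do not show that the 2 mutants are alike. These direct tests were run without a block only. The difference between the mutants was 1.78 ± 0.78 for Il12b and 2.24 ± 1.21 for Il1b after Pam3CSK4 (adjusted p = 1 for both).

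**Figure D4:**
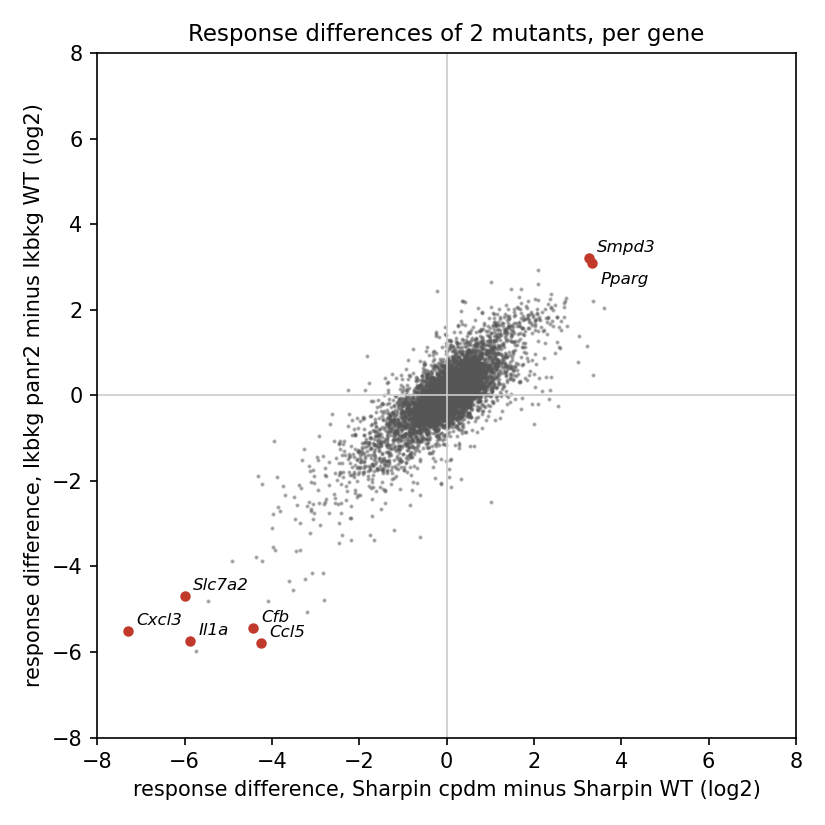
Response difference (log2) of Sharpin cpdm (horizontal axis) and Ikbkg panr2 (vertical axis) for each of the 8489 genes called in the wild-type response; points are genes, and 7 are named in red. The correlation across genes was 0.792.

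Atf3 KO macrophages differed from Bl6 WT in few genes. After Pam3CSK4 Il2ra, the alpha chain of the IL-2 receptor, was higher by 2.52 ± 0.36, the endosomal GTPase Rab4a by 1.72 ± 0.21 and the transporter Mfsd7c, now Flvcr2, by 1.29 ± 0.24. Against the same stimulated Bl6 WT arrays, Il2ra was also called higher in Il10 KO, and Rab4a in Il10 KO and Nfkb1 KO. Whether the shared controls account for this was not tested. Erdr1 was lower in Atf3 KO by -6.12 ± 0.77 after Pam3CSK4 (adjusted p = 0.000842) and, unstimulated, by -6.58 ± 0.77 (0.000284). Lower signals after Pam3CSK4 were also those of Apbb2 (-2.11 ± 0.35), Tarm1, an activating receptor (-1.72 ± 0.30), the actin-binding Palld (-1.68 ± 0.25), the acyl-CoA synthetase Acsl1 (-1.31 ± 0.23), the acid phosphatase Acpp (-1.29 ± 0.22) and Wwc2 (-1.01 ± 0.18). Unstimulated, the kinase subunit Camk2b was higher by 1.79 ± 0.24, and the receptors Pira2 (-1.73 ± 0.30) and Lilra6 (-1.43 ± 0.26) and the thyroid hormone deiodinase Dio2 (-1.54 ± 0.26) were lower. None of the cytokines and enzymes fixed in advance passed the threshold after Pam3CSK4, and their intervals leave larger changes open, such as -2.40 to 1.18 for Il1b. Il12b differed by 0.27 ± 0.55, Il6 by 0.16 ± 0.70, Tnf by 0.30 ± 0.67, Il1b by -0.61 ± 0.85, Nos2 by 0.33 ± 0.48, Ptgs2 by 0.29 ± 0.52 and Il10 by 0.82 ± 0.52, each with an adjusted p of 1. Megakaryocyte markers were lower as a list of 3, none called and 2 adjusted over the list alone (median -1.08, adjusted p = 7.67e-05; adjusted p = 0.0233 with an estimated correlation). Unstimulated, interferon-stimulated genes were higher as a list, with a median of 0.87 and none of 30 called, also adjusted over the list alone (adjusted p = 5.47e-25; adjusted p = 0.255 with an estimated correlation). Against the mean of the 2 other wild-type groups, a comparison chosen after seeing the data that is also given for the other knockouts, the median was 0.09, and -0.55 and 0.72 in the single arrays, and that of Bl6 WT itself was -0.82.

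Between Atf3 KO and Bl6 WT 13 genes differed after Pam3CSK4 (82 blocked) and 11 unstimulated (30 blocked). Without any 1 stimulated array the first count was 22 to 29, lowest without Bl6 WT replicate III and highest without either Atf3 KO replicate. The second was 5 without Atf3 KO replicate IV, 6 without either Bl6 WT replicate and 39 without Atf3 KO replicate III. For the response difference limma called 0 genes, also when blocked. An unadjusted p below 0.05 was reached by 258 genes, fewer than a share of 0.05 of the 20753 tested. The 0 calls therefore do not show that the responses are alike. Erdr1 and Rab4a passed whichever stimulated array was left out, and Erdr1 whichever unstimulated one. A further 3 lists after Pam3CSK4, 8 unstimulated and 4 for the response difference had adjusted p from 1.57e-22 to 0.0392, and an adjusted p of 0.0946 to 0.912 with an estimated correlation. The induced genes had a median response difference of -0.12 over 390 genes (camera p = 0.177 with an estimated correlation), which ranged from -0.19 without Sharpin WT unstimulated replicate II to -0.03 without replicate I, arrays that help to choose the genes.

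Il10 KO macrophages had higher cytokine and chemokine levels than Bl6 WT after Pam3CSK4. Of 15 cytokines 7 were higher (9 adjusted over the list alone), led by Csf2, the growth factor GM-CSF (+5.70 ± 0.62), with Csf1 at +3.36 ± 0.68, Il6 at +3.18 ± 0.70, Il1a at +3.09 ± 0.67 and Il12b at +2.57 ± 0.55. Of 19 chemokines 6 were higher (10 adjusted over the list alone), among them Ccl17 (+3.79 ± 0.48), Cxcl5 (+3.42 ± 0.44), Cxcl3 (+3.15 ± 0.79) and Cxcl2 (+3.12 ± 0.70). The adjusted p was 2.15e-12 for cytokines and 6.15e-08 for chemokines, and the adjusted p was 0.0138 and 0.0357 with an estimated correlation. Ptgs2 was higher by 3.45 ± 0.52 and Nos2 by 2.41 ± 0.48 (adjusted p = 0.00113 and 0.0112), whereas Tnf differed by 1.78 ± 0.67 (0.228) and Il1b by 0.92 ± 0.85 (0.771). Macrophage identity genes were lower in 3 of 19 cases (9 adjusted over the list alone), including the complement subunits C1qa (-1.41 ± 0.33) and C1qc (-0.96 ± 0.17; adjusted p = 1.35e-07, and adjusted p = 0.0375 with an estimated correlation). Integrated stress response genes were higher in 4 of 17 cases (13 adjusted over the list alone), with the pseudokinase Trib3 at +3.35 ± 0.70 (adjusted p = 1.37e-10; adjusted p = 0.0912 with an estimated correlation).

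Other genes higher in stimulated Il10 KO were the aspartic protease Ctse (+4.72 ± 0.38), Inhba (+4.70 ± 0.66), the STAT5-induced inhibitor Cish (+4.62 ± 0.73), the chitinase-like Chi3l1, now Chil1 (+3.86 ± 0.64), and the aquaporin Aqp9 (+3.85 ± 0.44). Ctse and Aqp9 lay under the lower quartile in stimulated Bl6 WT, so that these 2 differences are lower bounds. Lower were Fgd2 (-2.79 ± 0.50), apolipoprotein E, Apoe (-2.50 ± 0.50), Tmem176a (-2.48 ± 0.58), Glrp1 (-2.35 ± 0.53), the phosphodiesterase Gdpd2 (-2.27 ± 0.57) and Rab3il1 (-2.21 ± 0.30). The replication helicase subunit Mcm6 (-2.21 ± 0.54), thrombomodulin, Thbd (-2.19 ± 0.23), and syndecan 1, Sdc1 (-2.18 ± 0.43), were lower as well. Ctse, Chi3l1, Ptgs2 and Mcm6 lie within 100 tested genes of Il10 on its chromosome. A further 6 lists had adjusted p from 7e-06 to 0.019, and an adjusted p of 0.303 to 0.986 with an estimated correlation. In all, 447 genes differed, 295 higher and 152 lower, and 1488 in the blocked fit. The count was 83 without Il10 KO replicate IV, 122 without Bl6 WT replicate IV and 171 without Bl6 WT replicate III, all stimulated. Of the 24 genes past the threshold that were ranked by size or fixed in advance, 11 passed whichever array was left out, and Il6 and the Il10 signal were among those lost without any 1 of the 4. Of the other list members named, Il1a, Cxcl2 and C1qa were lost without any 1 as well, Cxcl3 held only without Bl6 WT replicate III and Trib3 only without Il10 KO replicate III, and C1qc was lost without Bl6 WT replicate III or Il10 KO replicate IV.

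Unstimulated Il10 KO macrophages had higher interferon-stimulated genes, with 8 of 30 called (28 adjusted over the list alone), a median of 1.80 and an adjusted p of 1.05e-45 (adjusted p = 0.0379 with an estimated correlation). Against the mean of the 2 other wild-type groups the median was 1.04, and 0.81 and 1.45 in the single arrays. Integrated stress response genes were higher, with Trib3 called (+3.86 ± 0.70) and 10 of 17 adjusted over the list alone, as were chemokines with Cxcl10 called (+3.87 ± 0.64) and 7 of 19 adjusted over the list alone. Effectors were higher in 3 of 20 cases (9 adjusted over the list alone), with Irg1 at +4.83 ± 0.81. The adjusted p of these 3 lists was 1.24e-16, 9.46e-07 and 1.49e-12. With an estimated correlation the adjusted p was 0.0377, 0.0379 and 0.0377. Ctse (+6.42 ± 0.38) and the glycine transporter Slc6a9 (+3.75 ± 0.46) were higher, and the adhesion molecule Vcam1 (-2.50 ± 0.48), the complement receptor Vsig4 (-2.30 ± 0.43), Abca9 (-1.95 ± 0.36), the lipase Mgll (-1.94 ± 0.38) and Fam78b (-1.91 ± 0.30) lower.

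In all, 67 genes differed between unstimulated Il10 KO and Bl6 WT, 53 higher and 14 lower, and 443 in the blocked fit. Without Bl6 WT replicate III there were 7, without Il10 KO replicate IV 10, without Bl6 WT replicate IV 19 and without Il10 KO replicate III 209. Only Ctse and Slc6a9 of the 10 named genes passed whichever array was left out. The response difference was called for 13 genes (44 blocked), 9 positive and 4 negative, or 8 and 2 after quantile normalization. Among them were Csf2 (+5.56 ± 0.88), Inhba (+5.32 ± 0.93), Ccl17 (+3.69 ± 0.67), tissue factor, F3 (+2.63 ± 0.34), the proteoglycan Lum (+2.40 ± 0.33), Il10 (-4.81 ± 0.73) and Serpinb10-ps, now Serpinb10 (-2.59 ± 0.47). The count was 0 without Bl6 WT unstimulated replicate III, 3 without replicate IV, 8 without Bl6 WT stimulated replicate IV and 22 without replicate III. It was 20 without Il10 KO unstimulated replicate III and 34 without the stimulated array of that bioreplicate. A further 8 unstimulated lists and 10 lists for the response difference had adjusted p from 5.57e-35 to 0.0471, and an adjusted p of 0.0571 to 0.747 with an estimated correlation. Induced genes had a median response difference of -0.29 (camera p = 0.0504 with an estimated correlation), and -0.13 without Il10 KO unstimulated replicate IV. Over genes induced at least 2-fold it was -0.25 (camera p = 0.0126 with an estimated correlation).

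In Nfkb1 KO macrophages after Pam3CSK4, the list of MHC class I presentation genes was higher than in Bl6 WT, with 5 of 14 called (13 adjusted over the list alone), including the peptide transporter subunit Tap2 (+1.53 ± 0.19) and the immunoproteasome subunit Psmb10 (+1.35 ± 0.21). Interferon-stimulated genes were higher in 4 of 30 cases (18 adjusted over the list alone), with Ifit2 at +3.28 ± 0.86, a call lost without any 1 of the 4 arrays, and Oasl1 at +2.02 ± 0.43. The adjusted p was 1.09e-14 and 3.46e-17, and the adjusted p was 0.0764 and 0.375 with an estimated correlation. MHC class II genes were higher in 2 of 8 cases (3 adjusted over the list alone), with H2-Ob at +1.92 ± 0.33 (adjusted p = 0.00033; adjusted p = 0.397 with an estimated correlation). Cell death and survival genes were higher in 2 of 19 cases (7 adjusted over the list alone), including the BH3-only Pmaip1 (+1.49 ± 0.38; adjusted p = 0.000293, and adjusted p = 0.0764 with an estimated correlation). Among 15 cytokines 4 were higher (6 higher and 4 lower adjusted over the list alone), including Tnfsf15 (+4.43 ± 0.60), Il12b (+2.41 ± 0.55) and Tnf (+2.51 ± 0.67), the last lost without any 1 of the 4 arrays (adjusted p = 0.0253 for the list; adjusted p = 0.515 with an estimated correlation). Il6 differed by -2.57 ± 0.70 (adjusted p = 0.0502, blocked 0.016), Il1b by 0.05 ± 0.85 (0.996) and Ptgs2 by 0.53 ± 0.52 (0.81), and Il10 was lower by -3.40 ± 0.52 (0.00064). Glycolysis and hypoxia genes were lower in 2 of 19 cases (3 adjusted over the list alone), with Pfkfb3 at -2.48 ± 0.27 (adjusted p = 7.69e-05; adjusted p = 0.409 with an estimated correlation).

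Besides Tnfsf15, which ranked between Fam26f and Cst7, the largest rises in stimulated Nfkb1 KO were those of the transcriptional repressor Gfi1 (+4.73 ± 0.73), Fam26f, now Calhm6 (+4.64 ± 0.73), the cystatin Cst7 (+3.98 ± 0.41), Clca3, now Clca1 (+3.59 ± 0.19), the sulfotransferase Hs3st3a1 (+3.54 ± 0.29) and Nos2 (+3.48 ± 0.48). Clic5 (+3.41 ± 0.26), the activation marker Cd69 (+3.40 ± 0.51) and Fam46c, now Tent5c (+3.39 ± 0.61), were next. The largest falls were those of Lcn2 (-6.36 ± 0.56), Arg1 (-5.97 ± 0.88), the gelatinase Mmp9 (-4.94 ± 0.83), Fgl2 (-4.37 ± 0.83), the incretin receptor Gipr (-4.18 ± 0.42) and the dicarboxylate transporter Slc13a3 (-3.72 ± 0.72). The lipid phosphatase Ppap2a, now Plpp1 (-3.52 ± 0.37), the aggrecanase Adamts4 (-3.35 ± 0.24) and the RNA-binding Igf2bp2 (-3.30 ± 0.47) were lower too. Gipr lay under the lower quartile in stimulated Nfkb1 KO, so that its fall is a lower bound. A further 5 lists had adjusted p from 0.00537 to 0.0268, and an adjusted p of 0.35 to 0.701 with an estimated correlation. In all, 632 genes differed, 439 higher and 193 lower, and 1569 in the blocked fit. The count was 297 without Bl6 WT replicate III, 355 without Bl6 WT replicate IV, 362 without Nfkb1 KO replicate IV and 405 without Nfkb1 KO replicate III, all stimulated. Of the 22 genes past the threshold that were ranked by size or fixed in advance, 18 passed whichever array was left out. Of the other list members named, Tap2, Psmb10 and Pfkfb3 passed each time, Ifit2 and Pmaip1 were lost without any 1 of the 4 arrays, Oasl1 without Bl6 WT replicate IV or Nfkb1 KO replicate III, and H2-Ob without Bl6 WT replicate III.

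Unstimulated, 2 genes differed between Nfkb1 KO and Bl6 WT, Rab4a (+1.43 ± 0.21) and the zinc transporter Slc39a4 (-2.27 ± 0.33), each with an adjusted p of 0.0201, and 41 did in the blocked fit. There were 0 without Bl6 WT replicate III, 24 without Nfkb1 KO replicate IV, and 1405 at an unadjusted p below 0.05 in limma with all arrays. Rab4a was also called higher in stimulated Atf3 KO, Il10 KO and Nfkb1 KO, which share the Bl6 WT controls. Unstimulated interferon-stimulated genes were higher as a list, with a median of 1.16, none of 30 called and 20 adjusted over the list alone (adjusted p = 7.7e-25, and adjusted p = 0.526 with an estimated correlation). Against the mean of the 2 other wild-type groups it was 0.34, and 0.63 and 0.21 in the single arrays. A further 6 unstimulated lists and 3 for the response difference had adjusted p from 2.14e-06 to 0.03, and an adjusted p of 0.362 to 0.598 with an estimated correlation. The response difference was called for 65 genes, 39 positive and 26 negative, and for 220 in the blocked fit. It was positive for Nos2 (+4.30 ± 0.68), cyclin D2, Ccnd2 (+3.84 ± 0.80), Clca3 (+3.76 ± 0.27), Hs3st3a1 (+3.21 ± 0.41) and Tmem132e (+3.13 ± 0.28). It was negative for Lcn2 (-6.08 ± 0.79), Saa3 (-5.69 ± 1.21, adjusted p = 0.0474, blocked 0.0608), Gipr (-4.17 ± 0.60), the pantetheinase Vnn3 (-3.45 ± 0.52) and Adamts4 (-3.33 ± 0.34). The count was 31 without Bl6 WT unstimulated replicate IV, 32 without replicate III and 35 without Nfkb1 KO unstimulated replicate III. Of the 10 named genes 8 passed whichever array was left out, and Ccnd2 and Saa3 did not. Induced genes had a median response difference of -0.06 over 390 genes (camera p = 0.107 with an estimated correlation), which turned to 0.01 without Nfkb1 KO unstimulated replicate III.

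Medians of gene lists are set side by side here, without a test of the difference between mutants. After Pam3CSK4 the median of the cytokine list was -1.41 in Sharpin cpdm, -1.64 in Ikbkg panr2, 2.42 in Il10 KO and 0.72 in Nfkb1 KO, and the adjusted p was 0.0869, 0.00365, 0.0138 and 0.515 with an estimated correlation. The median of the cell cycle list was 1.30, 1.70, -0.88 and -0.51 in the same order, and the adjusted p was 0.365, 0.22, 0.523 and 0.701 with an estimated correlation. With the stromal marker level as a covariate the first 2 of these medians were -0.003 and 1.06. Across genes, the response difference of Sharpin cpdm correlated with that of Atf3 KO at r = 0.375, of Il10 KO at -0.071 and of Nfkb1 KO at 0.033, and the matching rho was 0.374, 0.015 and 0.018. Leaving out 1 array moved these r values widely. That of Atf3 KO ranged from 0.092 without Sharpin cpdm unstimulated replicate II to 0.562 without replicate I, and that of Nfkb1 KO from -0.108 to 0.18 without the same arrays. That of Il10 KO ranged from -0.145 without Bl6 WT stimulated replicate III to 0.079 without replicate IV. Differences between the 2 comparison groups of each mutant, which hold no genotype effect, correlated across genes at -0.048, -0.282 and 0.052 for the same pairs, with a sign that depends on the order of the groups. Among stimulated calls, 114 genes were called in opposite directions in Sharpin cpdm and Il10 KO (11.3 by chance), while 12 were lower in both (4.21 by chance) and 4 higher in both (6.01). In Sharpin cpdm and Nfkb1 KO 79 were called in opposite directions (16.1 by chance), 35 were lower in both (5.35 by chance) and 14 higher in both (8.95). The knockouts share Bl6 WT arrays, which alone would give a correlation near 0.5 in simulated data. Observed values were 0.175 for Atf3 KO with Il10 KO, 0.309 for Atf3 KO with Nfkb1 KO and 0.208 for Il10 KO with Nfkb1 KO. The simulation held independent noise and no genotype effect, so values below 0.5 do not show that the knockouts are less alike than shared controls would make them.

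**Figure D5:**
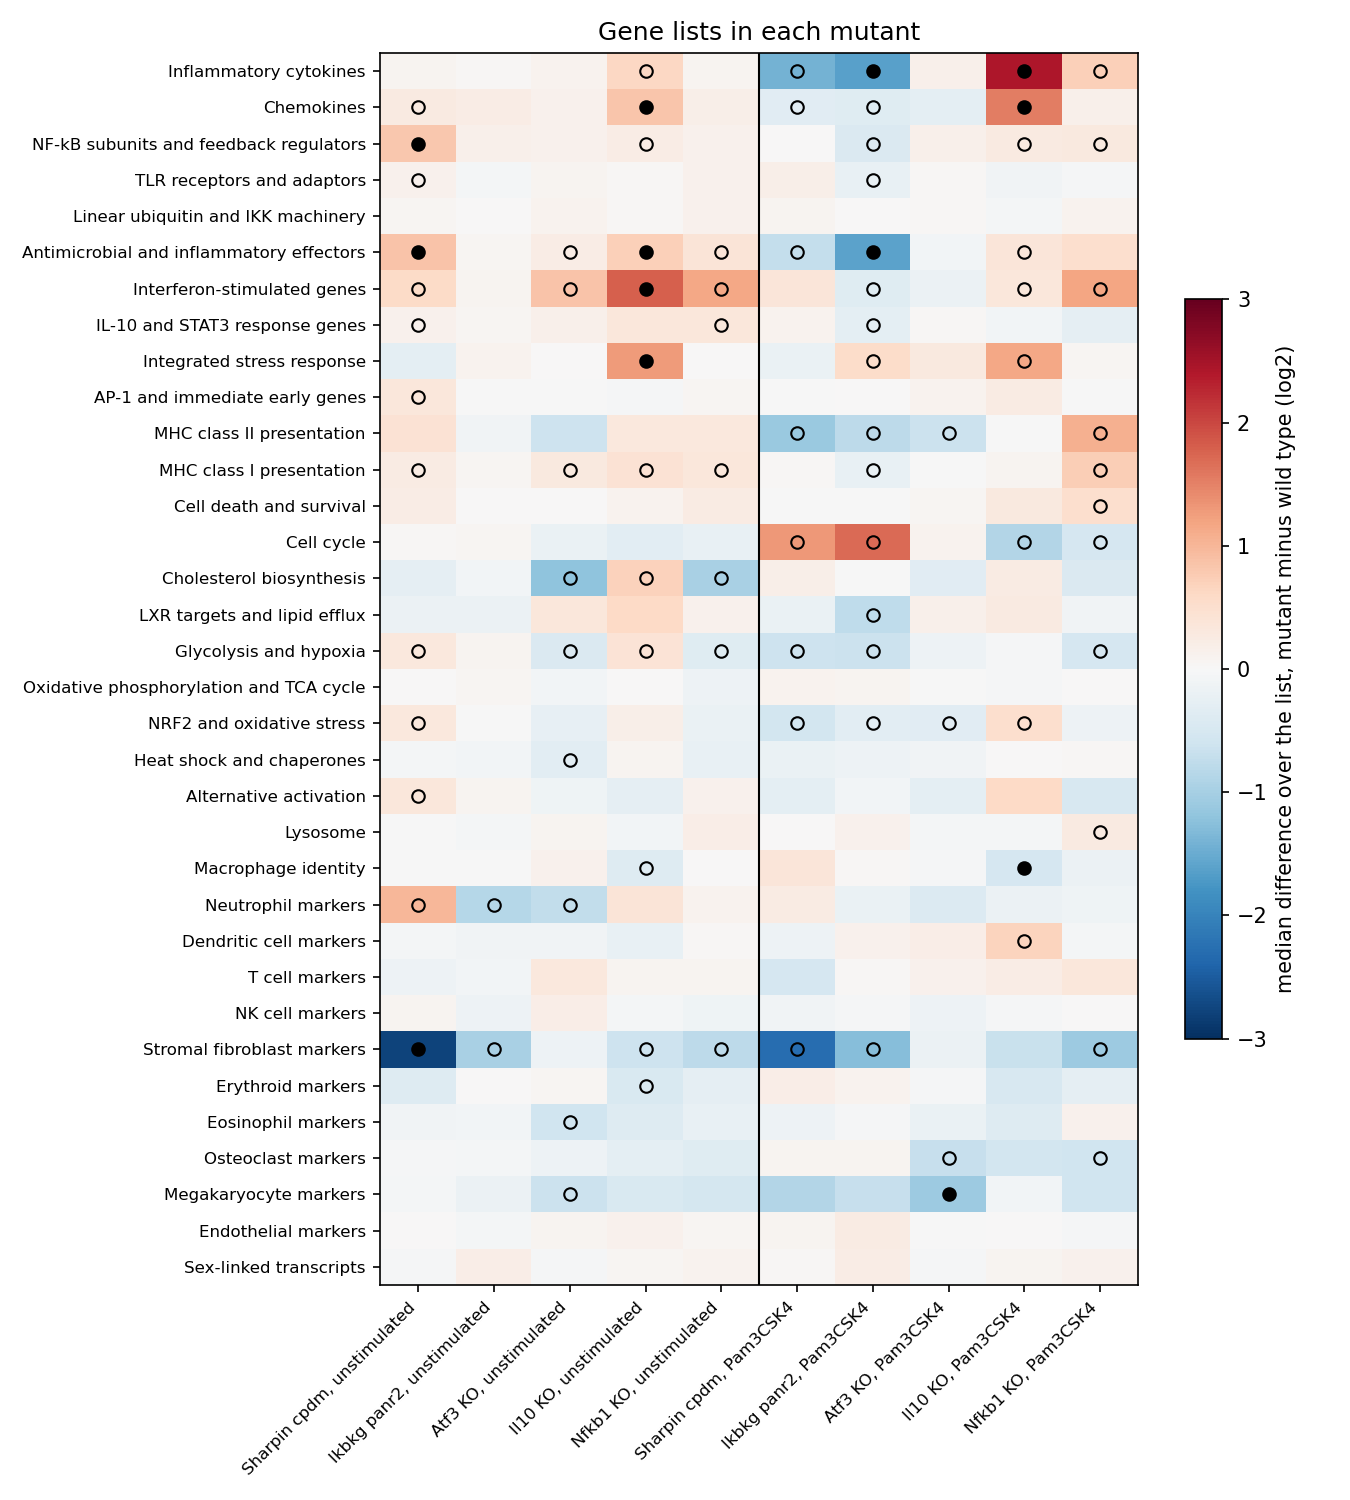
Median difference over each gene list (rows), mutant minus wild type (log2, colour), for each mutant and condition (columns); circles mark an adjusted p below 0.05 with the preset correlation, filled where it also holds with an estimated one. The stromal fibroblast list had its lowest median, -2.78, in unstimulated Sharpin cpdm.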

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

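The tests with stromal markers as a covariate, with a curve removed from each array, of interferon-stimulated genes against the other wild-type groups, and of the chromosomes of genes called in Atf3 KO were chosen only after the result was seen.

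The response to Pam3CSK4 differed from that of the wild type, by a test of the difference itself, for 166 genes in Sharpin cpdm, 50 in Ikbkg panr2, 13 in Il10 KO and 65 in Nfkb1 KO. Between Sharpin cpdm and Ikbkg panr2, the mutant's difference from wild type differed for 7 genes after Pam3CSK4 and for 2 unstimulated genes. The 7 included Shisa3 (+3.46 ± 0.61), Sprr2d (+1.90 ± 0.32) and Mctp1 (-1.63 ± 0.28) besides Enpp2 and Tbc1d2. For the wild-type response, chance assignment of arrays was argued against. With the 12 wild-type arrays alone the real split gave 9106 genes. It was the 1 split of 32 that part every bioreplicate to give as many, the highest other giving 317. A share of 1 in 32 is the smallest that this count can give. A further 100 splits of the 12 arrays held the real one and others drawn at random. Again only the real one gave as many, and the highest other gave 221. In other splits the response itself adds to the residual spread, which keeps their counts low. Groups of 2 give too few splits for such a count in the mutants.

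The lower induction in Sharpin cpdm and Ikbkg panr2 came with lower stromal fibroblast markers in the mutant arrays, so fewer stromal cells in the mutant cultures are a candidate explanation. With the marker level as a covariate and 1 slope per condition, the induced-gene shift of Ikbkg panr2 was -1.147, and -1.204 to -1.13 with 1 array left out. This cannot decide the question, since the slopes rest only on differences between the 2 arrays of each group. The marker level is also not cell content alone. After Pam3CSK4, Dcn rose from 6.74 to 8.03 and Lum from 5.09 to 6.39 in Ikbkg WT replicate V, while Cxcl12 fell from 7.26 to 6.48. In Sharpin cpdm the shift was -1.299, but it reached -0.506 without Sharpin WT unstimulated replicate I, the next highest being -1.123. Unstimulated Sharpin WT replicate II was itself high in these markers, at 9.70, against at most 7.72 in unstimulated Bl6 WT and Ikbkg WT arrays. In comparison group II the unstimulated markers were at 9.70 in Sharpin WT and 6.19 in Sharpin cpdm, with a shift of -0.94. In group I they were at 7.92 and 5.70, with a shift of -1.47. These values rest on 1 array per genotype and condition and cannot decide. In both mutants fewer stromal cells and an effect of the mutation on macrophages therefore cannot be told apart. A version with 1 slope for both conditions, run first, gave -1.312 for Sharpin cpdm and -1.33 for Ikbkg panr2. A level-dependent curve remaining in the deposited values is argued against in both. Whether the authors' normalization itself distorted the values was not tested, since array medians and lower quartiles were already nearly equal. After a loess curve was removed from each array the shift was -1.258 in Sharpin cpdm (-1.517 to -0.923 with 1 array left out) and -1.333 in Ikbkg panr2 (-1.393 to -1.225), while other genes moved by at most 0.12 and 0.17. Genes repressed at least 4-fold were shifted the other way, by 0.82 and 1.12, which no single factor per array would give. An effect of the genotype on the macrophages stays open in both.

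As a list, interferon-stimulated genes were higher in all 3 unstimulated knockouts than in the shared Bl6 WT arrays with the preset correlation. With an estimated one the adjusted p was 0.0379 in Il10 KO, 0.255 in Atf3 KO and 0.526 in Nfkb1 KO, and in the last 2 none of 30 genes was called. A low level in the Bl6 WT arrays is a candidate explanation. The list's median in Bl6 WT lay -0.82 from the mean of the other wild-type groups. Against that mean Il10 KO was higher, with a median of 1.038 and 0.81 and 1.45 in its single arrays, which argues against low Bl6 WT arrays as the whole cause. Atf3 KO stood at 0.092 (-0.55 and 0.72) and Nfkb1 KO at 0.34 (0.63 and 0.21), and there the low controls and an effect of the mutation cannot be told apart, since the arrays spread as widely as the shift. These were 1 test divided by mutant and reworded after its values were seen, and the wild-type stocks differ in more than this list.

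The few genes called in Atf3 KO may lie in donor-strain DNA kept next to the mutated gene. Of the called genes with a known position 94.1%, 16 of 17, lay on other chromosomes than Atf3, with an exact interval of 71.3 to 99.9%, which argues against such DNA as the place of these genes as a set. The remaining 5.88%, Gm10516, lay within 100 tested genes of Atf3, where 0.863% would by chance (exact hypergeometric p = 0.137). For that 1 gene donor DNA and an effect of the mutation cannot be told apart, since a single gene is too few to decide. This was 1 test divided after its values were seen.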

How the results depend on the processing

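The fits with the stromal marker level as a covariate were chosen only after the result was seen; the other alternatives were planned.

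Quantile normalization, centring on the 75th percentile and eBayes with trend and robust options left the 16 counts of called genes within 1.5 times their value. They left each correlation within its spread between comparison groups, and each induced-gene shift with the same sign and call. Over all alternatives that left out no array, 2612 results for single genes kept direction and call, 298 lost the call, 10 gained it and 2 reversed. For lists 1178 kept the call, 177 lost it and 8 reversed. These list counts pool settings that differ widely. In camera with an estimated correlation between genes, 122 list results lost the call and 23 kept it. Most list calls thus depend on the preset correlation between genes. With 1 array left out, 1717 gene results kept the call, 547 lost it, 1 gained it and 11 reversed. For lists 711 then kept the call, 135 lost it and 10 reversed. Averaging the probes of a gene was not run. Signals near the lower quartile of an array limit what can be read from genes silent in 1 condition. Unless stated, the cause was not tested.

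With the replicate block the counts after Pam3CSK4 were 2342 for Sharpin cpdm, 1065 for Ikbkg panr2, 82 for Atf3 KO, 1488 for Il10 KO and 1569 for Nfkb1 KO. Unstimulated they were 202, 2, 30, 443 and 41 in the same order, and for the response difference 799, 225, 44 and 220 for Sharpin cpdm, Ikbkg panr2, Il10 KO and Nfkb1 KO. The correlation of Sharpin cpdm with Il10 KO was -0.064, and of the gene results 1 lost and 4 gained the call, while 12 list results lost it. With the bioreplicate as a random block the response difference was called for 1192 genes in Sharpin cpdm, 477 in Ikbkg panr2, 1 in Atf3 KO, 162 in Il10 KO and 522 in Nfkb1 KO. With only the groups of the comparison in the fit, which leaves fewer residual degrees of freedom, stimulated counts were 0 in Atf3 KO, 12 in Il10 KO and 17 in Nfkb1 KO. Unstimulated counts were then 0 in Sharpin cpdm, 0 in Atf3 KO, 1 in Il10 KO and 0 in Nfkb1 KO, and response differences 21 in Sharpin cpdm, 198 in Ikbkg panr2, 4 in Il10 KO and 0 in Nfkb1 KO.

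Without a filter the Il10 KO response difference gave 8 genes and the correlation of Sharpin cpdm with Il10 KO was -0.064. With the stricter filter, which tests fewer genes, the counts were 5586 for the wild-type response, 296 and 406 for stimulated Il10 KO and Nfkb1 KO, 31 for unstimulated Sharpin cpdm, and 2 and 39 for the response differences of Il10 KO and Nfkb1 KO. The alternative activation list reversed there in the response difference of Ikbkg panr2, from -0.038 to 0.01. Over all genes the correlation of Sharpin cpdm with Ikbkg panr2 was 0.672. With an estimated correlation the shifts of Atf3 KO (-0.118, p = 0.177), Il10 KO (-0.293, p = 0.0504) and Nfkb1 KO (-0.058, p = 0.107) lost the threshold. Over genes induced at least 2-fold the shift was -0.04 in Atf3 KO, no longer past the threshold, and reversed to 0.021 in Nfkb1 KO, while in Il10 KO it was -0.246 and passed also with an estimated correlation (camera p = 1.21e-06 and 0.0126).

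With the stromal marker level as a covariate and 1 slope for both conditions, 143 genes were called in stimulated Sharpin cpdm, 164 in stimulated Ikbkg panr2 and 1 in unstimulated Sharpin cpdm. The response difference was called for 211 genes in Sharpin cpdm and 55 in Ikbkg panr2. These 2 counts do not test the stromal explanation, since 1 slope hardly moves a response difference where both conditions have similar marker levels. Reversed values for Sharpin cpdm were 0.379 for stimulated Sparc, 0.008 for unstimulated Col1a1, -0.003 for the stimulated cell cycle list, and -0.289 and -0.092 for the unstimulated glycolysis and NRF2 lists. For Ikbkg panr2 they were 0.086 for the stimulated MHC class II list, 0.071 and 0.031 for the stimulated and unstimulated stromal list, and 0.059 for alternative activation in the response difference. For the stromal list and its members the covariate is built from the same genes.

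With 1 array left out, the wild-type response gave 7373 to 8474 genes. Stimulated counts ranged from 211 to 644 in Sharpin cpdm, 63 to 230 in Ikbkg panr2, 22 to 29 in Atf3 KO, 83 to 451 in Il10 KO and 297 to 405 in Nfkb1 KO. Unstimulated counts ranged from 20 to 305, 1 to 12, 5 to 39, 7 to 209 and 0 to 24 in the same order, and response differences from 54 to 196, 12 to 68, 0 to 12, 0 to 34 and 31 to 80. Shifts ranged from -1.541 to -0.898 in Sharpin cpdm, -1.407 to -1.186 in Ikbkg panr2, -0.19 to -0.025 in Atf3 KO, -0.422 to -0.125 in Il10 KO and -0.23 to 0.014 in Nfkb1 KO, the last value without Nfkb1 KO unstimulated replicate III. Correlations with Sharpin cpdm ranged from 0.577 to 0.815 for Ikbkg panr2, 0.092 to 0.562 for Atf3 KO, -0.145 to 0.079 for Il10 KO and -0.108 to 0.18 for Nfkb1 KO.

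The lists that reversed with 1 array left out ranged as follows: in the response difference of Ikbkg panr2, alternative activation from -0.646 to 0.412 and interferon-stimulated genes from -0.795 to 0.074; in that of Il10 KO, cholesterol biosynthesis from -0.9 to 0.124. In unstimulated Sharpin cpdm glycolysis ranged from -0.174 to 0.66 and IL-10 and STAT3 response genes from -0.071 to 0.612, and in unstimulated Il10 KO the NF-kB list from -0.093 to 0.538. Genes that reversed, none past the threshold with all arrays, ranged in stimulated Atf3 KO from -0.257 to 0.801 for Il12b, -0.686 to 0.999 for Il6, -0.01 to 0.666 for Nos2, -0.221 to 0.793 for Ptgs2 and -0.358 to 0.953 for Tnf. Stimulated Il1b ranged from -0.261 to 0.366 in Nfkb1 KO, and Tnf from -0.26 to 0.068 in Sharpin cpdm and -0.519 to 0.137 in Ikbkg panr2.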

Other observations

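The values here were chosen for mention only after the result was seen, and none was tested for a cause. Within single genotypes, limma called 5090 genes for the response of Sharpin WT, 3551 of Bl6 WT and 3511 of Ikbkg WT. It called 2914 in Sharpin cpdm, 1290 in Ikbkg panr2, 4068 in Atf3 KO, 3244 in Il10 KO and 4875 in Nfkb1 KO. Cholesterol biosynthesis genes, 18 tested, differed as a list in the unstimulated knockouts, with a median of -1.21 in Atf3 KO, 0.70 in Il10 KO and -0.96 in Nfkb1 KO (camera adjusted p = 2.17e-14, 0.000373 and 4.62e-05). With an estimated correlation the adjusted p was 0.255, 0.501 and 0.549. The Y-linked transcripts Ddx3y and Eif2s3y were high in all arrays of Ikbkg WT and Ikbkg panr2, at 11.17 and 12.52 in unstimulated Ikbkg WT replicate V, and low in the other 6 genotypes, at 4.87 and 5.17 in unstimulated Bl6 WT replicate III. Genes called in Il10 KO included 12 of 426 within 100 tested genes of Il10, where 5.84 would lie by chance (exact hypergeometric p = 0.0146, adjusted over the 5 mutants 0.073). For Sharpin cpdm it was 14 against 12.4, for Ikbkg panr2 6 against 4.44 and for Nfkb1 KO 10 against 5.99 (exact hypergeometric p = 0.359, 0.285 and 0.0781). Genes named above that lie this near include Serpinb10-ps for Il10, Ndrg1 for Sharpin and Clca3 for Nfkb1.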
